A study of Arabidopsis thaliana with 6 samples.

How the data were processed

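Gene expression was measured in whole plants of Arabidopsis thaliana, per the labels. The plants were 4-week-old seedlings harvested after 6 h in 120 mM NaCl. Of the 6 samples, 3 came from wild-type plants and 3 from plants that overexpress ThERF1, an ethylene response factor gene of another species (as background, of the salt-tolerant shrub Tamarix hispida). The design text describes 3 independent biological replicates per genotype. How many transgenic lines were used is not given in the sources used here. The replicate numbers below follow accession order within a genotype and pair no samples.

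Each sample was labelled with Cy3 and hybridised alone to an Agilent Arabidopsis array of the 4 x 44K format, design 021169. Per the file headers, the scanner images were read with Agilent Feature Extraction 10.7.1.1, and gProcessedSignal is an intensity on a linear scale after background subtraction and detrending within the array. The deposited gMeanSignal and gBGMedianSignal columns are raw spot and local background intensity. The deposited series table of the same arrays holds log2 values. It had 43663 values per array, of which 43603 matched a probe of the scanner files. Each of its 6 columns had a median of 9.41, and across probes each correlated with the log2 processed signal of its own array at r of at least 0.998. The scale of the authors' log2 table is thus known from the values, it is not centred on 0, and single-colour values have no direction of a ratio. At the same rank its columns differed by at most 9.41e-04, as after quantile normalization. No label or file header used here describes that step.

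The array held 43803 non-control spots for 43603 probes. Probes were named through the reference table of assembly TAIR10.1: 34358 by an unversioned transcript accession, 1880 by a locus in the file's gene name and 29 by a locus in the description. The other 7336 kept the file's own identifier. Probe positions are those of the array files, whose header names the genome build ath1:Jan2004. No position was taken from the reference table, since its assembly differs. It served for names and for which genes are neighbours. Whether a probe lies in an exon or a UTR was not analysed here.

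Values were log2(gProcessedSignal) minus each array's 75th percentile over non-control probes, so that a value of 0 is the 75th percentile of that array. Control spots and spots marked as outliers were left out, which removed between 352 and 667 spots per array, and no spot was saturated. Spots of one probe were averaged. A probe was kept where it was well above background on all 3 arrays of at least 1 genotype, and of several kept probes of a gene the one with the highest mean was used. At least 2 values per genotype were required. This left 21850 genes, of which 19331 have a locus. Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Differences are ThERF1 minus wild type on the log2 scale with their SE. No untreated array is among the samples, so a response to salt was not tested. The number of arrays limits the precision. The number of probes well above background ranged from 29674 to 32434 per array.

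Where a gene was well above background on all arrays of one genotype and on none of the other, the fold is a bound. It sets the bright genotype's mean against the dim genotype's mean of, per array, the higher of the probe's own value and the lowest value among probes well above background.

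Before the data were examined, 28 gene lists were fixed from memory with 512 loci. Of these, 478 carried the listed symbol as symbol or synonym in the reference table, and the other 34 carried another or no name there. None of the latter symbols was the main symbol of another locus, so no member was dropped. Lists were tested with camera (preset inter-gene correlation of 0.01) on the 21661 genes measured on all 6 arrays, with Benjamini-Hochberg adjustment over the 26 lists that had at least 5 members. Camera with an estimated correlation and fry were run beside it. Camera compares a list with the other genes. The p of fry tests whether a list's own genes move, on balance, one way.

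The rule for named genes, also fixed before the data were examined, took 4 kinds of genes. The first were genes past the threshold, well above background on all 6 arrays and with no overlap between genotypes: the 10 largest rises and 10 largest falls that have a symbol or a locus, or all where fewer passed. The second were genes past the threshold and well above background on 3 arrays of one genotype and none of the other, the 3 largest bounds per direction. The third were up to 4 members of each list with the smallest p, and the fourth the reference genes. Probes of the same or near-identical family members can share signal, which was not tested.

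Alternatives fixed in advance were quantile normalization, normexp background correction (offset 50) before the 75th percentile or quantile step, the median in place of the 75th percentile, no filter on dim probes, a filter on all 6 arrays, eBayes with trend and robust options, the mean over a gene's probes, the authors' log2 table, slide as a block, a threshold of 0.01 and leaving out each array in turn. Dim-probe filters were set on all 6 arrays when an array was left out. With slide as a block the genotype difference comes from slide 1, which has 1 ThERF1 array, and the 43 genes with no value on that array had no estimate. The arrays of slide 1 alone, a scaling to the spike-in probes and differences with dim values set at the lowest bright signal (the lowest value among probes well above background on that array) were added after seeing the data. The test was run on simulated arrays drawn from the 21661 genes' means and spreads, 10 times with 200 changed genes each. For this comparison limma called 43.6% of genes changed 2-fold, 91.2% of those changed 4-fold and 97.7% of those changed 8-fold, and 5.95% of all calls were unchanged genes. Spreads were those moderated by eBayes, and noise was independent for each gene and array. The simulated arrays thus held no slide effect and no array that stood apart, so these shares need not hold for the samples. With 1 list shifted by 0.5 in each of 10 such simulations of 21661 genes, camera called it 10 times with the preset correlation and 4 times with an estimated one, and fry 6 times. Noise was drawn independently for each gene, so the simulated lists held no correlation among members. In the data the estimated correlation was 0.33, 0.003, 0.58 and 0.24 for the jasmonate, defence, glucosinolate and peroxidase lists. The simulations therefore cannot show whether the preset correlation is right for these lists.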

Results

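Transcript levels were measured on 6 single-colour arrays, 1 per sample. Of these, 3 held whole wild-type Arabidopsis plants and 3 held plants that overexpress ThERF1, all kept in 120 mM NaCl for 6 h. The 75th percentile of the processed signal ranged from 3443 to 6129 intensity units, with the highest in wild type replicate 2. Between 68.1% and 74.4% of probes were well above background. All wild-type arrays and ThERF1 replicate 1 shared slide 1 and scan 1, and ThERF1 replicates 2 and 3 shared slide 2 and scan 2. ThERF1 itself, a gene of another species, was not analysed here, so the labels were not checked against its level.

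Across genes, which are not independent replicates, r was 0.984 to 0.988 within the ThERF1 group, 0.954 to 0.985 within wild type and 0.958 to 0.979 between the groups. Wild type replicate 2 lay apart from the other wild-type arrays. The first principal component held 46.2% of the variance and placed wild type replicate 2 at 36.4, against -57.1 and -42.7 for wild type replicates 1 and 3. The ThERF1 arrays lay between 0.208 and 38.2.

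**Figure D1:**
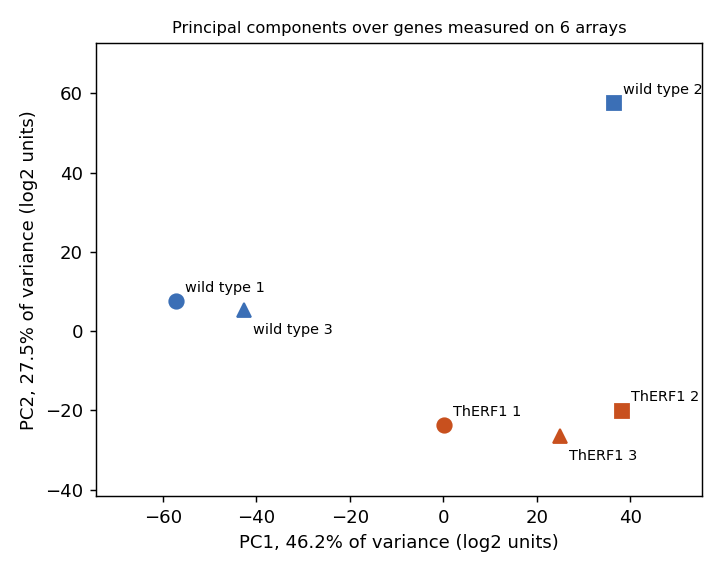
First and second principal components (log2 units) of the genes measured on all 6 arrays, with 1 point per array and colour by genotype. Wild type replicate 2 lies at 57.5 on the second component, and the other 5 arrays lie between -26.5 and 7.66.

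The comparison asked which transcripts differ between ThERF1 and wild-type plants under salt. MRD1 (AT1G53480) was 28.3-fold higher in ThERF1 plants, a log2 difference of 4.82 with an SE of 0.20 (limma, adjusted p = 0.00383, 3 arrays per genotype). Its neighbour HEI10 (AT1G53490), which takes part in meiotic crossover formation, rose by 2.18 (SE 0.16, adjusted p = 0.0213). GAT1_2.1 (AT1G15040), annotated as a glutamine amidotransferase, rose by 1.76 (adjusted p = 0.0321), and AT5G01740, of unknown function in the array annotation, rose by 1.69 (adjusted p = 0.027). In the array's own build, ath1:Jan2004, the MRD1 probe lies on chromosome 1 from 19967163 to 19967222 and the HEI10 probe from 19970145 to 19970204.

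More of the called transcripts were lower in ThERF1 plants. Regulators among them were PAP1 (AT1G56650), a MYB activator of anthocyanin synthesis, which fell by 1.76 (SE 0.11, adjusted p = 0.0213), ERF105 (AT5G51190), an ethylene response factor, which fell by 1.82 (SE 0.15, adjusted p = 0.0321), and ARR6 (AT5G62920), a cytokinin response regulator, which fell by 1.33 (adjusted p = 0.0347). AT1G73325, annotated as a Kunitz protease inhibitor, fell by 2.77 (SE 0.20, adjusted p = 0.0213). Genes with roles in carbohydrates or the cell wall were AT5G62360, annotated as an invertase or pectin methylesterase inhibitor, which fell by 1.86, TBL26 (AT4G01080), which fell by 1.83, and the beta-amylase gene BAM5 (AT4G15210), which fell by 1.80. The putative adenylosuccinate lyase genes AT4G18440 and AT1G36280 fell by 1.91 and 1.77, and AT1G75960, annotated as an AMP-binding protein, fell by 1.69. A second probe of AT1G36280 gave -0.22, so its probes disagree, and its annotation matches that of AT4G18440, with which it may share signal on the array. Adjusted p of the last 6 genes lay between 0.027 and 0.0418.

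In ThERF1 plants 3 further lower transcripts were not well above background on any array. FH3 (AT4G15200), a formin that binds actin, was at least 1.60-fold lower, the unnamed probe A_84_P767684 at least 1.55-fold and AT4G01380, annotated as plastocyanin-like, at least 1.51-fold. FH3 and BAM5 are neighbours in the reference table. The other 5 called transcripts lie outside the naming rule and are named here after their values were seen. AT5G03090 was well above background on 1 wild-type array and 7.34-fold higher in ThERF1 plants with dim values set at the lowest bright signal of their array. AT5G49130, a MATE efflux family gene, was at least 1.14-fold lower, and the sugar transporter gene SWEET7 at least 1.47-fold from 2 wild-type values. A transcript described in the array file as MAF5 had 2 ThERF1 values, with its probe well above background in neither, and was 2.74-fold lower with these set at that signal. An unnamed transcript differed by -1.40.

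**Figure D2:**
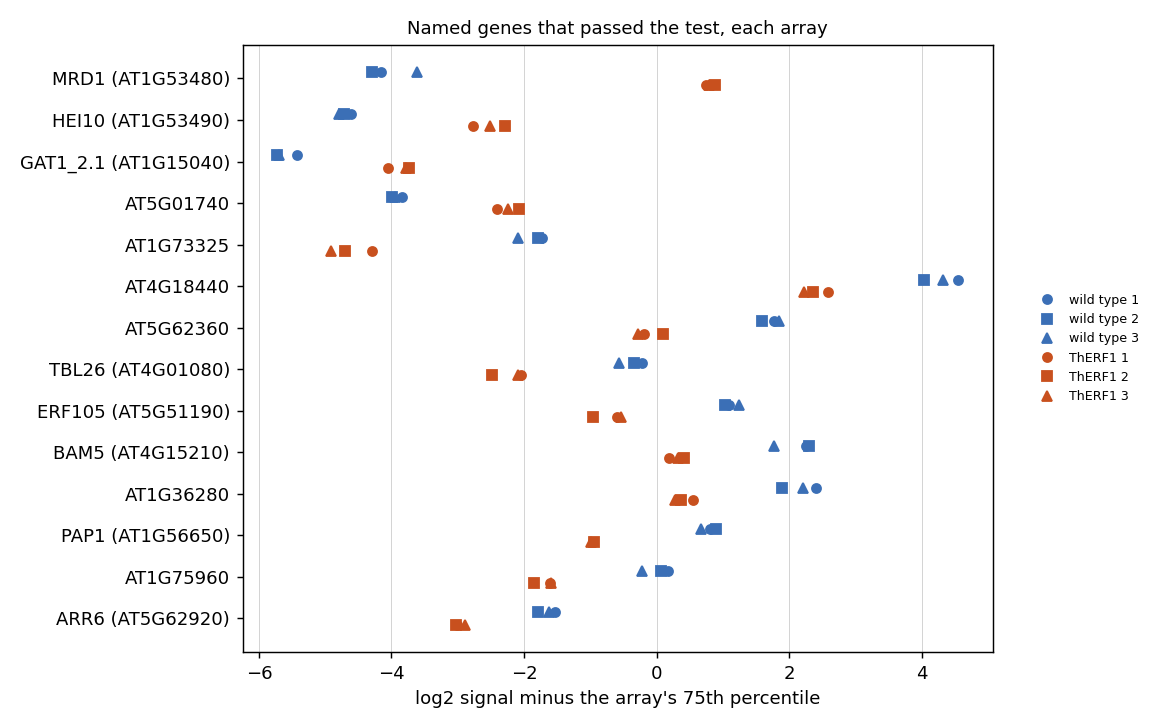
Normalized log2 signal per array (0 is the 75th percentile of the array) for the named genes well above background on all arrays, with 1 point per array, wild type in blue and ThERF1 in orange. The genotypes do not overlap for any gene shown, and MRD1 lies at -4.02 in wild type and 0.80 in ThERF1 plants on average.

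In total 22 of 21850 genes passed the test, 5 higher and 17 lower, and 2412 had an unadjusted p under 0.05. Detection was uneven too. Over all genes of the array, 143 were well above background on all wild-type and no ThERF1 arrays, and 8 the other way. Wild type replicate 1 with ThERF1 replicates 1 and 2, set against the other arrays, gave 3 and 131. Such an imbalance is thus not particular to genotype. With dim values set at the lowest bright signal of their array, 17 of the 22 differed at least 2-fold and 5 did not. Values of the genotypes did not overlap for 3819 genes (17.5%). The 10% that chance gives is a mean over all splits of the arrays. Genes are not independent, so a single split can depart from that mean without an effect of genotype. For 9 called genes, 11 further probes were well above background on at least 3 arrays. Of these, 10 had the same direction and a difference of at least 2-fold. The further probes of HEI10, GAT1_2.1 and AT1G75960 were above background on 3 arrays and that of TBL26 on 4. The genotype with the higher signal may thus have admitted them. Several of the 11 were of the same gene, AT5G62360. Slide 2 held no wild-type array, so the difference with slide as a block was that of ThERF1 replicate 1 against wild type within slide 1, for all 21807 genes with an estimate. Both settings are thus 1 estimate from 1 ThERF1 array, and they differ only in the arrays behind the spread. Limma called 0 genes with slide as a block and 0 within slide 1, with 863 and 589 at an unadjusted p under 0.05. The 22 genes had absolute log2 differences of 1.29 to 4.77 there (adjusted p 0.227 to 0.669 with the block), in a direction fixed beforehand, since the genotypes do not overlap for any of the 22. The count rests on single arrays: limma called 0 genes without wild type replicate 1 (1832 at an unadjusted p under 0.05), 0 without ThERF1 replicate 2 (1334) and 0 without ThERF1 replicate 3 (1526), 1 without wild type replicate 3, 4 without ThERF1 replicate 1, and 229 (103 higher, 126 lower) without wild type replicate 2, all 22 included. Scaled to the spike-in probes, 57.1% of calls were higher (113 higher, 85 lower) against 22.7% here, and the median of all genes moved from 0.01 to 0.20. Under that scaling 1546 genes had an unadjusted p under 0.05, fewer than the 2412 here.

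Genes of jasmonate synthesis and signalling were lower in ThERF1 plants as a group. Of 23 measured, 22 had negative differences with a median of -0.72, 0 passed the limma test over all genes (16 had an unadjusted p under 0.05) and 15 were lower adjusted over the list alone. MYC2, the central transcription factor of the pathway, differed by -0.98 (SE 0.13, adjusted p = 0.0916), the repressor gene JAZ8 by -1.65 (adjusted p = 0.134) and OPR3, which encodes an enzyme of jasmonate synthesis, by -1.02 (adjusted p = 0.157). Camera called the list at an adjusted p of 1.79e-15, and it was 0.43 with an estimated correlation. In ThERF1 replicate 1 alone against wild type, which is all that slide as a block or slide 1 compares, the median was -0.59 (adjusted p = 1.94e-12 with the block and 2.77e-12 within slide 1, from an arm of 1 array). Pollen markers, 3 measured, had a median of -1.25 with dim values set at the lowest bright signal.

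Defence proteins under ethylene and jasmonate control moved in both directions. Over all genes limma called 0 of 10 (8 at an unadjusted p under 0.05), and adjusted over the list alone 6 were lower and 2 higher. The lower ones were the storage protein genes VSP2 (-1.26, SE 0.14, adjusted p = 0.0727 over all genes) and VSP1 (-1.19) and the plant defensin genes PDF1.2, PDF1.2b, PDF1.2c and PDF1.3 (-1.25 to -1.33), whose near-identical members may share signal. The higher ones were the chitinase gene HCHIB (1.21) and PR4 (0.45). The list median was -1.22 (camera adjusted p = 0.00111, and adjusted p = 0.43 with an estimated correlation). It was the 1 list that fry called (adjusted p = 0.0277). With slide as a block or within slide 1, where 1 ThERF1 array sets the difference, its median was -1.03 (adjusted p = 1.60e-04 and 1.63e-05).

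Glucosinolate synthesis genes were lower as a group, with 19 of 21 differences negative and a median of -0.72. Over all genes limma called 0 (12 at an unadjusted p under 0.05), and 2 were lower adjusted over the list alone. The regulator genes MYB34 and MYB76 differed by -1.25 and -1.30, and CYP79F1, an enzyme of aliphatic glucosinolate synthesis, by -0.81. Camera gave an adjusted p of 1.17e-08, and it was 0.665 with an estimated correlation. Relative to the mean of the 6 arrays, the glucosinolate median lay at 0.32, 0.59 and 0.03 in the wild-type and at -0.71, -0.36 and 0.05 in the ThERF1 replicates. ThERF1 replicate 3 was thus close to wild type replicate 3 and not below it. Class III peroxidases were higher as a group, with 20 of 22 differences positive and a median of 1.01. Over all genes limma called 0 of them (8 at an unadjusted p under 0.05), and 0 adjusted over the list alone. PRX52 differed by 1.07 and AT3G32980 by 0.95 (camera adjusted p = 2.15e-06, and adjusted p = 0.665 with an estimated correlation). On the same scale, the peroxidase median lay at -0.34, -0.93 and -0.03 in the wild-type and at -0.02, 0.79 and 0.58 in the ThERF1 replicates. Root markers, with 7 of 8 differences positive, lay at -0.24, -0.47 and -0.03 and at -0.06, 0.40 and 0.04. ThERF1 replicate 1 alone, which sets the difference by slide, gave medians of -1.06 for glucosinolates (adjusted p = 6.56e-17 with slide as a block and 2.85e-18 within slide 1) and 0.61 for peroxidases (0.0383 and 0.0343).

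**Figure D3:**
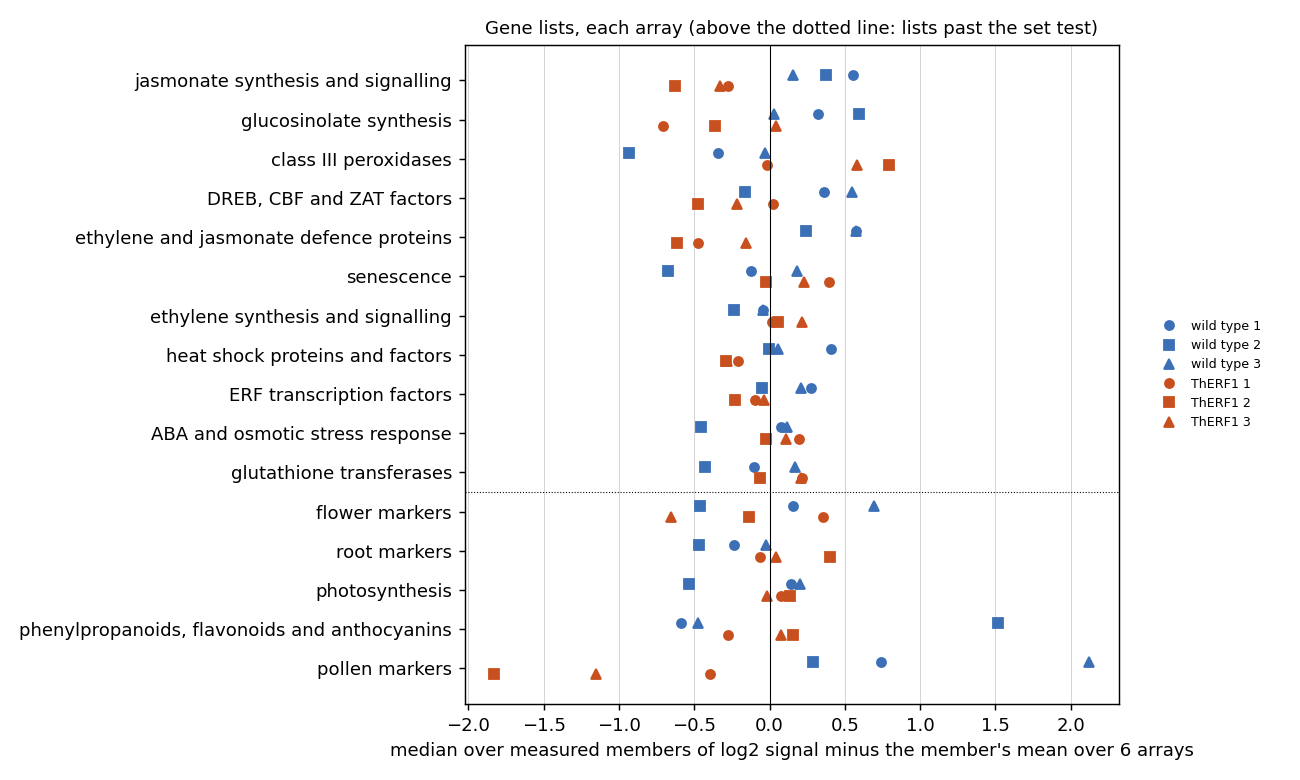
Median over a list's measured members of the log2 signal minus the member's mean over the 6 arrays, with 1 point per array, wild type in blue and ThERF1 in orange; lists called by camera stand above the dotted line. Jasmonate genes lie between 0.16 and 0.56 in wild-type arrays and between -0.63 and -0.28 in ThERF1 arrays, and wild type replicate 2 lies at 1.52 for phenylpropanoids, flavonoids and anthocyanins.

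Transcription factors of the ERF family were lower as a group, with 13 of 21 differences negative and 8 positive (median -0.27, camera adjusted p = 0.0174, and adjusted p = 0.665 with an estimated correlation). Among them 1 fell over all genes, ERF105, and 3 were lower adjusted over the list alone. ERF13 differed by -2.03 and ERF11 by -0.73, while ERF12 differed by 1.79. Of 12 DREB, CBF and ZAT factors, which act in cold, drought and salt responses, 11 differences were negative with a median of -0.42 (adjusted p = 3.63e-04, and adjusted p = 0.665 with an estimated correlation). Limma called 0 over all genes (5 at an unadjusted p under 0.05) and 0 adjusted over the list alone. CBF2 differed by -0.96 and STZ, also called ZAT10, by -0.76. Heat shock genes had a median of -0.70, with 8 of 13 differences negative and 5 positive (adjusted p = 0.0174, and adjusted p = 0.665 with an estimated correlation), with 0 called by limma over all genes (3 at an unadjusted p under 0.05) and 2 lower adjusted over the list alone. HSFA2, a heat shock factor, differed by -1.35 and HSP90.1 by -0.70. With slide as a block, from 1 ThERF1 array, the adjusted p was 0.0199 for ERF factors (median -0.22), 0.107 for DREB, CBF and ZAT factors (-0.28) and 0.102 for heat shock genes (-0.41), and within slide 1, the same comparison, it was 0.0262, 0.105 and 0.0836. Without wild type replicate 1 the adjusted p was 0.0901 for ERF factors and 0.0501 for heat shock genes (median -0.40), and without wild type replicate 3 the median of DREB, CBF and ZAT factors was -0.24 (adjusted p = 0.00999). Spike-in scaling gave a median of -0.08 for ERF factors (adjusted p = 0.00322) and -0.23 for DREB, CBF and ZAT factors (1.17e-05), and the mean over probes gave -0.10 for ERF factors (0.0474).

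Higher groups with smaller medians were senescence (0.36, camera adjusted p = 0.0121), ethylene synthesis and signalling (0.22, 0.0144), ABA and osmotic stress response (0.23, 0.0218) and glutathione transferases (0.24, 0.0463). Differences were positive for 12 of 15, 12 of 18, 21 of 28 and 14 of 20 genes. With an estimated correlation the adjusted p was 0.665 for ethylene and 0.721 for the other 3. Over all genes limma called 0 in each, with 1, 2, 7 and 6 at an unadjusted p under 0.05. Adjusted over the list alone, 1 gene was higher in the ethylene list, ERS2, an ethylene receptor gene (1.25, adjusted p = 0.181 over all genes), and 0 genes passed in the others. ABI5 and RAB18 of the ABA list differed by 1.45 and 0.76, the senescence regulator WRKY53 by 0.76 and GSTF3 by 0.81. Against the direction of their lists, COR15A of the ABA list differed by -0.85 and GSTU5 of the glutathione transferases by -0.78. Without wild type replicate 2, where these 4 lists lay at -0.67, -0.23, -0.46 and -0.43 relative to the mean of the 6 arrays, the medians were 0.13, 0.15, 0.07 and 0.15 (adjusted p = 0.501, 0.204, 0.949 and 0.642). Without wild type replicate 3 they were 0.62 for senescence, 0.35 for ABA and 0.41 for glutathione transferases (adjusted p = 8.04e-06, 3.21e-04 and 9.21e-04), and without ThERF1 replicate 2 the last was 0.36 (0.00462). Without ThERF1 replicate 1 the adjusted p was 0.0937 for senescence, 0.0876 for ABA and 0.216 for glutathione transferases, and without ThERF1 replicate 3 it was 0.0682 for ethylene and 0.125 for glutathione transferases. No filter on dim probes ended all 4 calls (adjusted p = 0.0800, 0.0735, 0.222 and 0.301), and normexp with the 75th percentile ended those of ABA (0.104) and glutathione transferases (0.117). The latter were also lost with the median as scale (0.0529) and with spike-in scaling (0.100), under which the 4 medians were 0.56, 0.41, 0.43 and 0.43. By slide, where ThERF1 replicate 1 alone sets the difference, the medians were 0.57, 0.02, 0.37 and 0.34 (adjusted p = 1.60e-04, 0.227, 0.00585 and 0.00585 with the block, and 1.65e-04, 0.23, 0.0061 and 0.0141 within slide 1).

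Lists of genes with direct roles in salt handling did not pass the test. Sodium and potassium transport had a median of 0.02 while camera pointed down (adjusted p = 0.736). HKT1, a sodium transporter gene, was not well above background on wild-type arrays and at least 2.94-fold higher in ThERF1 plants from 2 values (adjusted p = 0.0832). It and CBL10 (-0.55), a calcium sensor gene, made 1 higher and 1 lower adjusted over the list alone. Proline and other osmolytes had a median of -0.01 with camera pointing up (adjusted p = 0.736), with 0 adjusted over the list alone and P5CS2, of proline synthesis, at 0.36. GolS1, the member of that list with the smallest p, differed by -1.29. Superoxide dismutases, catalases and ascorbate peroxidases had a median of -0.02 with camera pointing up (adjusted p = 0.736), 0 adjusted over the list alone and CSD2 at 0.64. For these 3 lists limma called 0 genes over all genes, with 3, 3 and 1 at an unadjusted p under 0.05. By slide, from 1 ThERF1 array, their medians were -0.05, 0.07 and 0.14 (adjusted p = 0.672, 0.672 and 0.192 with the block, and 0.704, 0.704 and 0.168 within slide 1).

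Among the other lists, camera gave an adjusted p of 0.059 for early stress and calcium signalling (median -0.20, 1 lower adjusted over the list alone, WRKY18 at -0.86), 0.105 for phosphate starvation (-0.32), 0.121 for salicylate defence (0.22, PR5 at 1.33) and 0.186 for expansins, XTH and cellulose synthases (-0.19). It was 0.439 for phenylpropanoids, flavonoids and anthocyanins (-0.22), where PAP1 was the 1 gene lower, over all genes and adjusted over the list alone. For auxin response it was 0.566 (0.06 with camera pointing down), with WES1 higher adjusted over the list alone at 1.07 and IAA5 at -1.72. For iron it was 0.566 (-0.04) and for the circadian clock 0.567 (-0.14, LHY higher adjusted over the list alone at 0.78). The lists of phosphate, salicylate, cell wall and iron genes had 0 adjusted over the list alone, and outside PAP1 limma called 0 genes of these 8 lists over all genes, with 3, 2, 1, 5, 1, 4, 3 and 5 at an unadjusted p under 0.05 in the order given. Early stress genes passed with normexp and the 75th percentile (adjusted p = 0.0190), no filter on dim probes (0.00986), the filter on all 6 arrays (0.0447), trend and robust options (0.0474) and spike-in scaling (0.0255), and phenylpropanoid genes with spike-in scaling (0.0469). The camera calls given here used the preset correlation. With an estimated one over all 6 arrays, the adjusted p lay between 0.665 and 0.868 for these 8 lists. The estimated correlation was 0.69 for early stress and for phenylpropanoid genes. Single arrays changed several calls too. Early stress genes passed without wild type replicate 2 (adjusted p = 0.00453), ThERF1 replicate 1 (0.00628) or ThERF1 replicate 3 (0.0478), but had an adjusted p of 0.709 without wild type replicate 3. Phosphate genes passed without wild type replicate 1 (0.021) or ThERF1 replicate 1 (0.0358), and cell wall genes without wild type replicate 1 (0.00855). Salicylate genes passed without wild type replicate 3 (0.00699) or ThERF1 replicate 2 (0.00462), clock genes without wild type replicate 2 (0.0313), and phenylpropanoid genes as lower without wild type replicate 3 (0.0236) but as higher without wild type replicate 2 (median 0.39, 0.0046). By slide, where ThERF1 replicate 1 alone sets the difference, early stress genes had a median of 0.02, with camera pointing up with the block (adjusted p = 0.957) and down within slide 1 (0.973). Salicylate defence had a median of 0.40 in that comparison of 1 ThERF1 array (adjusted p = 1.59e-04 with the block and 1.32e-04 within slide 1). The medians of the others in it were -0.12 for phosphate, -0.18 for cell wall, -0.36 for phenylpropanoid, -0.14 for iron and -0.15 for clock genes, and -0.09 for auxin with camera pointing up. Their adjusted p lay between 0.0537 and 0.912 with the block and between 0.063 and 0.915 within slide 1.

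Tissue markers were included because whole plants can differ in their parts. Root markers had a median of 0.27 (8 measured, adjusted p = 0.217), photosynthesis genes 0.14 (26 measured, adjusted p = 0.218) and flower markers -0.27 (10 measured, -0.17 with dim values set at the lowest bright signal, adjusted p = 0.186), with 0 in each adjusted over the list alone and, by limma, 0, 1 and 0 at an unadjusted p under 0.05. With slide as a block or within slide 1, from 1 ThERF1 array, their medians were 0.07, 0.15 and 0.08. Flower markers passed without wild type replicate 2 (median -0.50, adjusted p = 0.0294) or ThERF1 replicate 1 (adjusted p = 0.0345). Photosynthesis genes passed as higher without wild type replicate 1 (adjusted p = 0.00953) or 3 (0.00467) and as lower without wild type replicate 2 (median -0.10, 0.0134). Under spike-in scaling root markers passed as higher (0.0145) and flower markers as lower (0.00322). All these calls used camera with the preset correlation. With an estimated correlation over all 6 arrays, the adjusted p was 0.665 for root, 0.868 for photosynthesis and 0.721 for flower markers. The estimated correlation of photosynthesis genes was 0.81. The 3 pollen markers measured, VGD1, VGDH1 and AGP6, differed by -2.62, -2.29 and -1.25, all lower adjusted over the list alone (0 called by limma over all genes, 3 at an unadjusted p under 0.05), and the probes of VGD1 and VGDH1 were well above background on 2 and 0 of the ThERF1 arrays. With dim values set at the lowest bright signal the differences were -2.43, -1.08 and -1.25. The 3 seed and embryo markers measured had a median of -0.85, or 0.21 with dim values so set, with 1 higher adjusted over the list alone, PAP85 (0 called by limma over all genes, 1 at an unadjusted p under 0.05). Both lists were too small for camera here. Without a filter on dim probes it tested both, and pollen markers were lower (adjusted p = 0.0149) while seed markers did not pass (0.463). The 8 reference genes differed by -0.21 to 0.29 (adjusted p = 0.378), with 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 by limma.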

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

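The arrays of slide 1 alone and the spike-in scaling were chosen after seeing the data. The direction of all 22 called genes, where tested, was the same in every alternative run, but the number of calls was not. For slide as a block, slide 1 alone and arrays left out, the direction was fixed, since the genotypes do not overlap for these genes. Against 5 higher and 17 lower genes there were 1 and 0 without a filter on dim probes, where more genes are tested, 0 and 0 with slide as a block, and 0 and 0 in slide 1 alone, which both rest on 1 ThERF1 array (limma, with 2694, 863 and 589 at an unadjusted p under 0.05). Lower genes numbered 10 with normexp and the 75th percentile, 11 with a filter on all 6 arrays and 11 with trend and robust options. Spike-in scaling gave 113 and 85, and an adjusted p under 0.01 gave 1 and 0. At the threshold of 0.05 the counts at a fitted difference of 2-fold were the same in these settings. Leaving out 1 array gave 0 to 103 higher and 0 to 126 lower genes, the highest without wild type replicate 2. By fitted difference, for genes higher at least 2-fold in ThERF1 plants the range was 0 to 96, and for genes lower at least 2-fold in ThERF1 plants 0 to 119. For the other settings named the cause was not tested. Quantile normalization with or without normexp, the median, the mean over probes and the authors' log2 table moved no count by over 1.5 times.

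Camera called 11 lists, and 9 to 14 in the other settings. With an estimated correlation it called 0, and fry called 1. The jasmonate, defence, glucosinolate and peroxidase lists were called with the preset correlation in every setting, though slide as a block and slide 1 alone are 1 comparison with 1 ThERF1 array. Without wild type replicate 2 the median of photosynthesis turned to -0.10 (adjusted p = 0.0134) and the median of phenylpropanoids, flavonoids and anthocyanins to 0.39 (adjusted p = 0.0046). Over all arrays left out, these medians ranged from -0.10 to 0.28 and from -0.69 to 0.39, and the cause was not tested. Medians of cell wall, sodium and potassium transport, and osmolyte genes also changed sign without wild type replicate 2. They were 0.09, -0.05 and 0.13 (camera adjusted p = 0.989, 0.555 and 0.915). That of early stress genes was then -0.46 (0.00453). Signal over background limits the bounds, since 68.1% to 74.4% of probes were well above it. The planned promoter motif alternatives were not run, as no genome sequence was used here.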

Other observations

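Chosen only after the result was seen were the splits for the gene count, the tests on wild type replicate 2 and on jasmonate genes, the test of flanking genes, the use of slide 1 alone and the setting of dim values. A cluster of genes on chromosome 4 was at 1 of 2 levels. It was low in wild type replicates 1 and 3 and high in wild type replicate 2 and every ThERF1 array. AT4G22505 stood at -7.95 and -8.20 in wild type replicates 1 and 3, at -0.65 in wild type replicate 2 and at -0.41, 0.01 and 0.07 in the ThERF1 replicates. AT4G22485, AT4G22490, AT4G22513 and AT4G22517 had the same pattern, as had AT3G05727 on chromosome 3 (-7.60 and -6.63 against -1.08, -0.18, -0.15 and -0.58). None passed the genotype test (adjusted p 0.372 to 0.545). These genes were picked by their values.

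Of 18 phenylpropanoid, flavonoid and anthocyanin genes, 14 were highest in wild type replicate 2, and C4H, PAL1, PAL2 and GSTF12 in another array. DFR, a late enzyme gene of the pathway, stood at 1.54 there, against -2.38 and -4.13 in the other wild-type arrays and -3.02, -1.81 and -1.99 in ThERF1 arrays. The median of the phenylpropanoid, flavonoid and anthocyanin list in that array was 1.52 above the mean of the 6 arrays, although PAP1 was at 0.89 there and at 0.81 and 0.67 in the other wild-type arrays. All 5 bright spike-in probes were lower on every ThERF1 array than on every wild-type array.

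The design cannot give a share of splits under 0.05, since 6 arrays make 10 splits. The real split called 22 genes and the highest other split 3, so 1 of the 10 called as many. With the preset correlation it called 11 lists, and 4 of the 10 splits called as many, with 5 in the lowest other and 14 in the highest other. With an estimated correlation every split called 0 lists. A camera call with the preset correlation is thus not particular to the split by genotype. The absolute medians of the jasmonate, defence, glucosinolate and peroxidase lists were 0.72, 1.22, 0.72 and 1.01 in the real split, against 0.45, 0.47, 0.70 and 0.85 in the highest other split. The split of wild type replicates 1 and 3 with ThERF1 replicate 1 against the rest, which keeps the slide 2 arrays together, had 4472 genes at an unadjusted p under 0.05 against 2412, which points to a structure of the samples beyond genotype. With slide as a block, which leaves ThERF1 replicate 1 alone against wild type, limma called 0 genes, with 863 at an unadjusted p under 0.05.

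Wild type replicate 2 lay apart from wild type replicates 1 and 3. Its lowest r with a slide 2 array exceeded its highest r with a wild-type array of its own slide by 0.00800. Slide 2 held only ThERF1 arrays, so this margin mixes slide with genotype. The slide is argued against for the place of wild type replicate 2, since all wild-type arrays shared slide 1 and scan 1. A ThERF1 sample under a wild-type label may account for it and stays open: over the 229 genes with the smallest p without the array in question, it lay nearer to the wild-type mean for 39.2%, wild type replicates 1 and 3 for 79.2% and 67.4%, and the ThERF1 replicates for 38.8%, 10.9% and 14.1%. Of these genes it lay nearer to wild type for 19.4% of those higher in ThERF1 plants, where the ThERF1 replicates gave 13.8% to 59.1%. For the lower ones the share was 55.6%, where the ThERF1 replicates gave 9.32% to 24.6%. AT4G22505 of the chromosome 4 cluster, picked by its values, stood at -0.65 in wild type replicate 2, near the ThERF1 replicates (-0.41, 0.01 and 0.07). Wild type replicates 1 and 3 were at -7.95 and -8.20. MRD1 went the other way, at -4.29 in wild type replicate 2, beside -4.16 and -3.61 in the other wild-type arrays. A trade between tissues stays open, since the highest of the root, green and flower medians in it was -0.46 and the quartiles of the root markers lie on both sides of 0, and a difference in growth or harvest stays open as untested.

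Jasmonate genes were lower in ThERF1 plants as a group. Limma called 0 of 23 over all genes, and the camera call was lost with an estimated correlation (adjusted p = 0.43). Slide stays open as a part of the lower jasmonate values, because the median within slide 1 was -0.59 but rests on 1 ThERF1 array there. A smaller share of flowers may contribute and stays open: the flower markers' median was -0.27, and with dim values set at the lowest bright signal their lower quartile was -0.56 and the median of the 3 pollen markers -1.25. Within slide 1 these medians were 0.08 and -1.10. The genotype difference that the design names stays open as untested, since neither the level of ThERF1 nor promoter motifs were analysed here.

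Of 19 called loci, 4 formed 2 neighbouring pairs, MRD1 with HEI10 and FH3 with BAM5. Of 10000 random draws of tested genes, 3 held as many pairs (permutation p of 4e-04), which argues against independent random placement. The draws treat genes as independent, so they cannot tell whether neighbours that vary together across arrays would give as many pairs. Among the other 9 splits of the arrays, with as many top genes, the highest number of pairs was 1. A wider change in copy number is argued against on the measured sides. There, 0 of 3 flanking genes were 2-fold different in the pair's direction (MSL4 -0.57, MUM4 -0.23, SDG2 -0.12). The flank beyond BAM5 was not measured, so a change reaching that way could not be seen. Shared local regulation and a sequence difference between the lines may each account for the pairs, and neither was tested.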
